A study of Mus musculus with 4 samples.

How the data were processed

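Ribosome footprint libraries of dorsal root ganglia from male mice treated with methylglyoxal were analysed, 4 libraries of 1 group, named replicates 1 to 4 as in the labels. Per the labels' protocols, ribosome-bound RNA was isolated on spin columns, rRNA was depleted, footprints were treated with phosphatase and selected at 28 to 34 nt on 15% gels, and libraries were made with a small RNA kit. 3' end libraries of RNA abundance, which the same protocol names, were not analysed here, so no translational efficiency was computed. Per the submitters' processing notes, FastQC 0.11.5, TopHat2 2.1.1, Bowtie2 2.2.9 and Cufflinks 2.2.1 were used with the mouse build GRCm38; the annotation, the counting rule, the treatment of reads with several matches and the strand setting are not given in the sources used here.

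The deposited table holds 48431 genes and 1 column per library. Its columns are named for TPM, but the values behave as CPM (reads per 1000000 reads): the authors' deposited values were whole multiples of 1 step per library, with a tolerance of 0.02 steps, for 96.9%, 97.0%, 97.0% and 96.5% of the values above 0 in replicates 1 to 4. The step did not depend on gene length: the share was 95.3% in the genes of the shortest exon length class (median 456 bases) and 97.4% in the longest (median 5834 bases) in replicate 1. The values were therefore used as CPM not divided by length, and each column sums to 1000000. The plan fixed before the data were examined assumed TPM, and its tests were kept on the CPM values. A log scale does not remove gene length, so contrasts between genes or lists and the percentiles of list levels include length differences. The step was worth 0.287, 0.380, 0.383 and 0.266 CPM, which gave library sizes of 3487636, 2633868, 2610536 and 3753018 reads. A count of 0 allows up to 3 reads. Values of long genes are raised relative to short ones at equal ribosome density, so levels were also computed per kb of coding length. Division by coding length takes all reads of a gene to lie in its coding sequence, which was not checked.

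Rows with the same symbol were summed. Of the gene IDs, 48052 were found in GENCODE M21 (GRCm38), which gave biotype, coordinates and coding length, and 379 were not. Genes with a mean of at least 1 CPM were called detected, and log2(value + 1) was used throughout, so a fold is on that scale and understates differences of low genes. Analyses were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Recovered reads of each 2 libraries were compared by a chi-square test over genes with at least 20 reads in both together. Only genes whose values were whole reads in all libraries entered this test. Because 2 pairs of libraries differed by little more than sampling noise, means and SDs are over the 2 pair means.

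Before the data were examined, 38 gene lists (37 with at least 3 detected members), 15 contrasts between lists, 24 between genes, the alternatives and the rule for named genes were fixed. The lists cover sensory neuron classes, sodium channels, sensory transduction, glia, Schwann cells, fibroblasts, vessels, immune and blood cells, muscle, fat, bone, spinal cord, the integrated stress response, eIF2, chaperones, detoxification, antioxidant genes, glycolysis, the translation machinery, mitochondria, injury, immediate early genes, cytokines, noncoding RNA and sex-linked genes. Genes named are the 30 with the highest mean, the 4 highest and 2 lowest detected members of each list, the genes of the contrasts, the 15 most variable genes with a mean of at least 10, the 5 least variable with a mean of at least 100, the Y-linked genes, Xist and members listed at 0. Genes named for shared sequence (mt-Co2, mt-Nd3 and mt-Nd4l) were chosen after their values were seen.

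A list's level was the median over its detected members, with its percentile among 10000 random lists of the same size. Contrasts were taken within each library and tested by a two-sided exact sign-flip permutation test with Benjamini-Hochberg adjustment over each family. Movement together was the SD over libraries of the members' mean deviation, set against 10000 random lists matched on level in 20 bins. Sequence shared between genes was counted as the share of a coding sequence's windows of 28 bases, the shortest footprint selected, that occur in an annotated transcript of another gene. This count covered only the ribosomal protein, mitochondrially encoded and oxidative phosphorylation lists and some of the most abundant genes. The steps were tested on simulated data: read totals were recovered within 0.0295% over 48431 genes, a list of 20 genes raised 1.5-fold in 1 pair came out at the 100th percentile, and 5 of 100 unchanged lists reached the 95th. Reads of the simulated genes were drawn independently, so genes that move together were not covered. Alternatives left out each replicate, changed the pseudocount to 0.1 or 5, the minimum mean to 0.1, 10 or none, kept the largest row per symbol, rescaled without mitochondrial and noncoding genes, scaled by the median ratio, or took the mean of list members. Alternatives added after seeing the data used each pair alone, coding length, genes whose values were whole reads in all libraries, or unshared windows. There was 1 group, so no comparison between groups was made.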

Results

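Ribosome footprints of mouse dorsal root ganglia, the clusters of sensory neuron cell bodies beside the spinal cord, were described in 4 libraries of 1 group. Per the labels, the ganglia came from male wild-type SW mice given methylglyoxal, a reactive dicarbonyl formed as a by-product of glycolysis, at 2 mg/kg by intraperitoneal injection for 6 days. The protocol text attached to the same samples speaks of saline, which goes against the treatment label, so the libraries are named here by the treatment label alone. Ribosome profiling sequences the short stretch of mRNA that a ribosome covers, here RNA of 28 to 34 nt, so that a gene's value follows how many ribosomes sit on its message. No control libraries were analysed here, and the comparisons are therefore between genes and gene groups within these libraries, and between the libraries themselves. The libraries held 3487636, 2633868, 2610536 and 3753018 reads for replicates 1 to 4, recovered from the step of which most values are whole multiples. The values are CPM (reads per 1000000 reads of the library, not divided by gene length), and at least 96.5% of those above 0 in each library are whole reads, while the rest are not. A count of 0 reads allowed up to 0.860, 1.14, 1.15 and 0.799 CPM in the 4 libraries, and this floor covers counting error only.

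The 4 libraries fell into 2 pairs. Replicates 1 and 2 (the first pair) differed by little more than sampling noise, as did replicates 3 and 4 (the second pair). Over genes with whole reads in all 4 libraries and at least 20 reads in the 2 libraries together, chi-square per degree of freedom was 1.03 and 1.05 within the pairs. It was between 3.27 and 4.01 across them. Simulated libraries of 1 pair gave 1.02, but a small random share of their values had also been shifted and all genes were kept. That value is therefore only a rough guide to sampling alone. The excess over sampling noise within the pairs was small but detectable with this many genes (chi-square test, p = 0.00999 and p = 0.000204). Each pair was therefore counted as 1 sample, and every mean ± SD below is over the 2 pair means (n = 2). The labels do not say whether the replicates came from separate animals, so the spread and the p-values describe these libraries and may be technical.

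**Figure D1:**
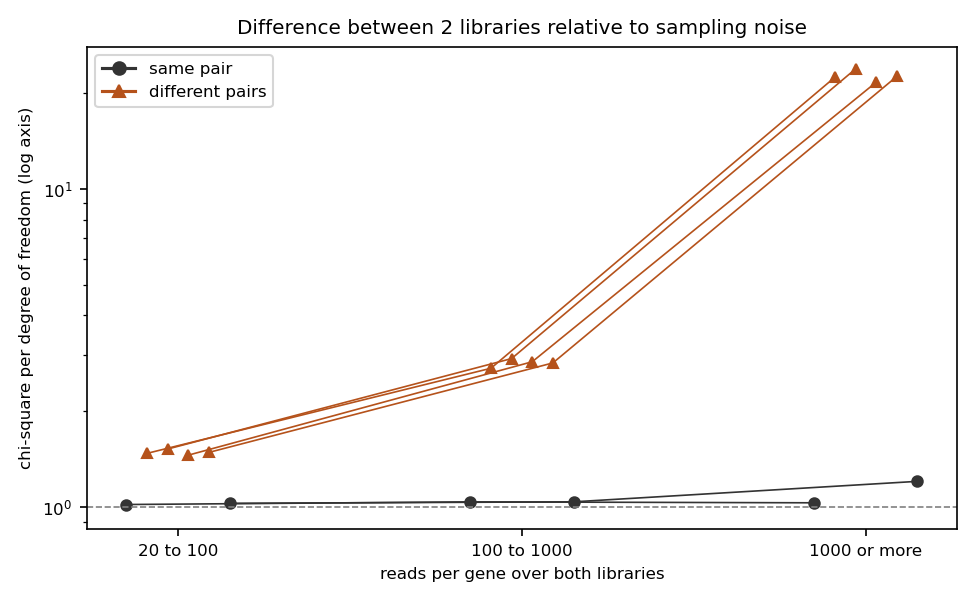
Chi-square per degree of freedom (log axis) of the reads of 2 libraries over genes, by the gene's reads in both libraries together, for all 6 combinations of the 4 libraries; the dashed line at 1 marks sampling noise. Libraries of the same pair stay between 1.02 and 1.21, while libraries of different pairs reach between 21.6 and 23.8 for genes with 1000 reads or more.

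Structural and mitochondrial RNA, myelin, matrix and cytoskeletal genes took the largest shares of the reads. The mitochondrial 16S rRNA gene mt-Rnr2 alone held 121167 ± 17455 CPM and the 12S gene mt-Rnr1 26251 ± 1372. Among genes annotated as coding, Lars2, the mitochondrial leucyl-tRNA synthetase gene, came first with 18957 ± 463 CPM. Where its reads lay along the transcript was not examined, so this rank need not reflect translation. The neuronal microtubule-associated protein gene Map1b stood at 9379 ± 955 and the type I collagen gene Col1a1 at 8949 ± 867 CPM. The myelin gene Pmp22 stood at 7484 ± 1117. The lipoprotein gene Apoe stood at 6686 ± 54.3 CPM, and the neurofilament genes Nefm and Nefl at 3466 ± 41.8 and 3217 ± 22.1. The vault RNA Vaultrc5, the RNase MRP RNA Rmrp and Gm24601, annotated as an rRNA gene, were the highest noncoding entries encoded in the nucleus at 7587 ± 175, 4820 ± 595 and 13578 ± 814 CPM.

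Protein-coding genes held 78.7% ± 0.980 of the reads, mitochondrial rRNA 14.7% ± 1.61 and nuclear rRNA genes 1.43% ± 0.0666 (SD, n = 2). The 10 most abundant genes held 23.2% ± 1.09 and the 100 most abundant 40.1% ± 0.850 of each library; without mitochondrial and listed noncoding genes the share of the first 10 was 11.5%. A mean of at least 1 CPM was reached by 15271 genes, of which 13820 were protein coding, and 14046 genes reached 1 in every library. A mean of at least 10 was reached by 8995 genes, of at least 100 by 1495 and of at least 1000 by 88. Across the detected genes, Pearson's r of log2 values was 0.981 and 0.983 within the pairs and 0.970 to 0.976 across them; genes are not independent replicates. The median SD of a gene over the 4 libraries was 0.20 on the log2 scale, and it was 0.32 for genes of 1 to 10 CPM, 0.16 for 10 to 100 and 0.09 above 100.

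Markers of the cells that make up the ganglion were nearly all detected. The fibroblast and extracellular matrix genes had the highest median of the cell-type lists, 10.06 ± 0.11 on the scale of log2(CPM + 1) over 19 detected members, led by Col1a1 and by Col1a2 and Sparc at 6464 ± 395 and 5396 ± 622 CPM. Myelinating Schwann cell genes followed with a median of 7.83 ± 0.01 over 20 members, satellite glia genes with 7.42 ± 0.01 over 14 members, non-myelinating and immature Schwann cell genes with 7.39 ± 0.07 over 13 of 14 members, and pan-neuronal genes with 7.36 ± 0.24 over 26 members. Besides Pmp22, the Schwann cell list held Mbp at 2184 ± 114 and Cd9 at 1368 ± 34.7 CPM, and Gjb1, a gap junction gene, was its lowest member at 28.0 ± 0.373. Of the neuronal genes, Tubb3 and Uchl1 stood at 1786 ± 27.4 and 1017 ± 13.1 CPM. Artn, which encodes a growth factor, was listed at 0 in all 4 libraries.

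Blood vessel, immune and neighbouring tissue genes lay lower, apart from skeletal muscle. Endothelial genes had a median of 4.81 ± 0.12 and mural cell genes 5.78 ± 0.38, macrophage genes 5.29 ± 0.10, red blood cell genes 5.40 ± 0.18, adipocyte genes 4.57 ± 0.48 and bone and cartilage genes 5.03 ± 0.26. The skeletal muscle list reached 7.41 ± 0.49 with all 14 members detected, led by Ttn at 850 ± 421, Myh4 at 641 ± 108 and Acta1 at 595 ± 216 CPM. The lymphocyte and neutrophil list (2.24 ± 0.28) and the list of spinal cord glia and neurons (2.2 ± 0.21) were the only 2 of 37 lists at or below the 5th percentile of 10000 random lists of detected genes, and the oligodendrocyte gene Mobp stood at 1.74 ± 0.102 CPM. Myelinating Schwann cell genes exceeded spinal cord genes by 5.63 ± 0.20 on the log2 scale and satellite glia genes by 0.41 ± 0.0041, and macrophage genes exceeded lymphocyte and neutrophil genes by 3.05 ± 0.18, each in 4 of 4 libraries. Neuronal genes lay below myelinating Schwann cell genes by a difference of -0.47 ± 0.24 (0 of 4 libraries higher), and endothelial below red blood cell genes by -0.58 ± 0.30. Neuronal and satellite glia genes differed by less than the spread, -0.06 ± 0.25, with neuronal genes higher in 2 of 4 libraries (exact sign-flip permutation test, two-sided, p = 0.625). The sign turned to 0.11 in the second pair alone and to 0.021 without replicate 1, and macrophage minus lymphocyte and neutrophil genes came to 1.68 with the mean over members and turned to -1.31 with a minimum mean of 10, where few lymphocyte and neutrophil members stayed. The excess of Schwann cell over spinal cord genes was 2.53 with that minimum and 4.75 with a pseudocount of 5.

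**Figure D2:**
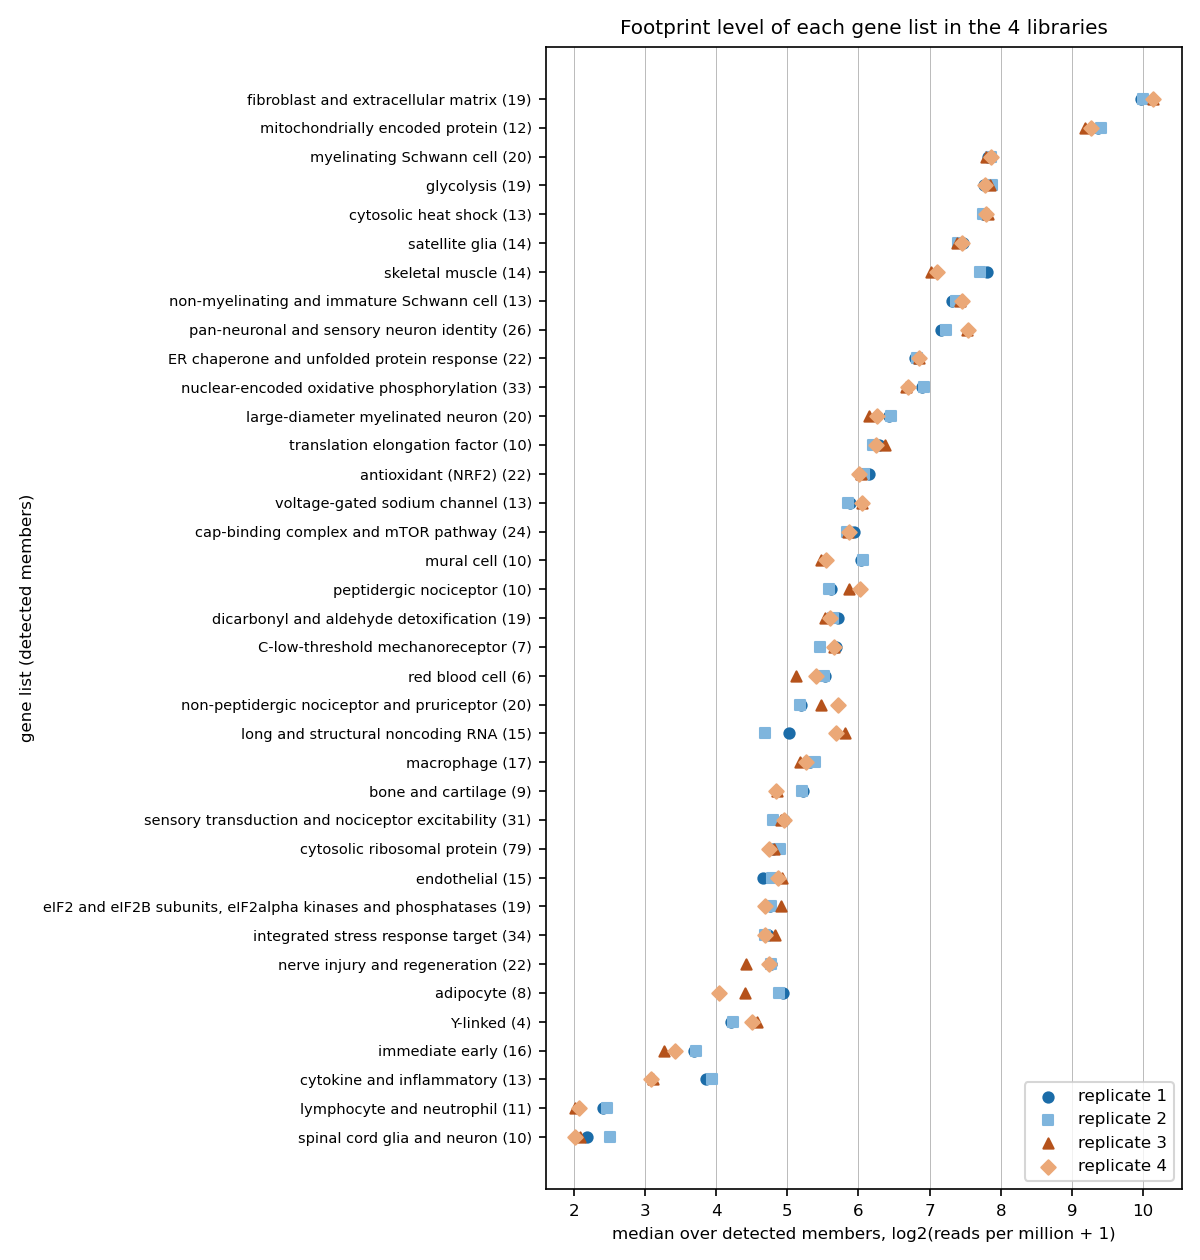
Median of log2(CPM + 1) over the detected members of each of 37 gene lists, 1 point per library; the number of detected members stands in parentheses. Fibroblast and extracellular matrix genes lie highest near 10.06 and spinal cord genes lowest near 2.2, and the skeletal muscle and noncoding RNA lists show the 2 pairs of libraries apart.

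Sensory neuron subtypes were all represented, with the large-diameter neuron genes highest in CPM. The large-diameter myelinated neuron list had a median of 6.33 ± 0.17 over 20 members, with Nefl and Nefh (2308 ± 226 CPM) in front. Peptidergic nociceptor genes followed with 5.77 ± 0.24 over 10 members, C-low-threshold mechanoreceptor genes with 5.61 ± 0.06 over 7 members, and non-peptidergic nociceptor and pruriceptor genes with 5.39 ± 0.28 over 20 members. The peptidergic list includes Nefm, which encodes a neurofilament of large neurons, so its highest member does not mark that subtype alone. Calca, which encodes the neuropeptide CGRP, stood at 531 ± 125 CPM, 9.71-fold above its paralog Calcb (53.5 ± 9.16) and 9.48-fold above Tac1, the substance P gene (54.8 ± 9.26). Mrgprd and P2rx3, a receptor and an ATP-gated channel of non-peptidergic nociceptors, stood at 329 ± 103 and 321 ± 91.5. Large-diameter genes exceeded non-peptidergic genes by 0.94 ± 0.45 and peptidergic genes did so by 0.39 ± 0.04, in 4 of 4 libraries each. Leaving out genes under 10 CPM turned the second of these to -0.67, since the lists then kept only their higher members. Per kb of coding length the peptidergic difference was 1.38 and the large-diameter one 1.05, so the order of these 2 lists turns with length.

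Among the voltage-gated sodium channels, which carry the neuronal action potential, Scn11a, Scn7a and Scn10a led. Scn11a (Nav1.9, chromosome 9, 119753759 to 119825456, GRCm38) stood at 1476 ± 214 CPM, Scn7a, also expressed by non-myelinating Schwann cells, at 1363 ± 2.83, Scn10a (Nav1.8, chromosome 9, 119608456 to 119719322) at 1019 ± 131 and Scn9a (Nav1.7, chromosome 2, 66480080 to 66634962) at 306 ± 40.9. Scn9a lay 3.32-fold below Scn10a, and Scn10a 1.45-fold below Scn11a, in all 4 libraries, and the order was the same per kb of coding length. Scn3a was the lowest detected member at 4.24 ± 0.945, and the list of 13 detected channels had a median of 5.96 ± 0.13. The sensory transduction and excitability list had a median of 4.91 ± 0.04 over 31 members, led by the mechanically gated channel gene Piezo2 (549 ± 49.8), P2rx3 and the calcium channel subunit gene Cacna2d1 (217 ± 6.97). Trpv1 (82.1 ± 6.11), the capsaicin receptor gene, exceeded Trpa1 (64.5 ± 7.72), an irritant receptor gene, 1.28-fold in 4 of 4 libraries. Nefh exceeded Prph (739 ± 4.04), which encodes peripherin of small neurons, 3.11-fold, a log2 difference of 1.64 that was 0.54 per kb of coding length.

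Genes that remove methylglyoxal and other aldehydes lay below the glycolytic genes. Against random lists of detected genes, their median was at the 99.8th percentile. The dicarbonyl and aldehyde detoxification list had a median of 5.62 ± 0.08 over 19 of 21 members, against 7.82 ± 0.01 for the 19 glycolysis genes and 6.07 ± 0.06 for the 22 antioxidant genes. Glo1 (chromosome 17, 30584936 to 30626871), which encodes glyoxalase 1, the first enzyme of methylglyoxal removal, stood at 29.1 ± 0.363 CPM and lay 1.90-fold below Hagh, the glyoxalase 2 gene (chromosome 17, 24840143 to 24864450), at 56.3 ± 3.86, and 3.08-fold below Park7 at 92.0 ± 10.2, in all 4 libraries. The log2 difference from Hagh was -0.93, and -0.54 per kb of coding length. From Park7 it was -1.62, and -1.72 per kb. The aldehyde dehydrogenase gene Aldh2 led the list at 279 ± 28.1, and the aldehyde reductase gene Akr1a1 (131 ± 0.955) exceeded Akr1b3 (40.8 ± 0.929) 3.16-fold. Fn3k, which encodes a kinase that reverses protein glycation, and Aldh1b1 were the lowest detected members at 7.16 ± 1.94 and 3.30 ± 0.783. Glycolysis exceeded detoxification by 2.2 ± 0.07 in 4 of 4 libraries, led by Aldoa (1162 ± 42.5), Pkm (463 ± 11.6) and Gpi1 (439 ± 26.5), and detoxification lay below the antioxidant genes by a difference of -0.45 ± 0.02, which was -1.14 per kb of coding length. Aldoa exceeded its paralog Aldoc 8.38-fold, and Ldha (228 ± 4.22) lay 1.45-fold below Ldhb (332 ± 5.76). Sequence shared with other genes was not counted for these paralogs or for Glo1, Hagh and Park7, so the folds may partly reflect shared reads. The highest antioxidant genes were Fth1 (400 ± 19.6), Cat (268 ± 8.26), Txn1 (212 ± 10.1) and Prdx2 (183 ± 3.10), and Nqo1, a target of the transcription factor NRF2, was the lowest at 11.5 ± 0.695.

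Genes of the integrated stress response, in which phosphorylated eIF2alpha slows initiation, lay below the endoplasmic reticulum chaperones. Integrated stress response targets had a median of 4.74 ± 0.03 over 34 of 36 members and the eIF2 and eIF2B genes with their kinases and phosphatases 4.78 ± 0.03 over 19 members. Slc38a2, an amino acid transporter gene, led the targets at 606 ± 72.6 CPM, whereas the transcription factor genes Atf4 (chromosome 15, 80255184 to 80257541) and Ddit3 stood at 23.7 ± 1.90 and 5.92 ± 1.03 and Trib3 at 1.48 ± 0.0665. Atf4 exceeded Ddit3 3.58-fold in 4 of 4 libraries (1.84 on the log2 scale, and 0.95 per kb of coding length) and differed from Atf5 (21.7 ± 3.68) by 0.13 ± 0.12, with Atf4 higher in 3 of 4. Of the eIF2alpha kinases, Eif2ak3 (PERK, chromosome 6, 70844515 to 70905245) stood at 28.7 ± 2.80, Eif2ak1 at 21.6 ± 4.39, Eif2ak2 at 16.9 ± 0.403 and Eif2ak4 (GCN2) at 13.0 ± 1.31. Eif2ak3 exceeded Eif2ak4 2.13-fold in 4 of 4 libraries and also per kb of coding length, but per kb it lay below Eif2ak2 and Eif2ak1 and Atf4 lay below Atf5. The constitutive phosphatase subunit gene Ppp1r15b (19.9 ± 1.65) exceeded the inducible Ppp1r15a (6.00 ± 0.200) 3.01-fold. Reads in untranslated regions were not separated from coding reads in any of these genes. The comparisons therefore need not follow the translation of the proteins.

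Chaperone genes of the endoplasmic reticulum had a median of 6.83 ± 0.02 over 22 members, above the integrated stress response targets by 2.1 ± 0.0082 in 4 of 4 libraries. Hsp90b1 (1195 ± 22.6), Canx (839 ± 81.1), Hspa5 (776 ± 55.5) and Calr (732 ± 22.0) led, with Hspa5, which encodes BiP, 1.54-fold below Hsp90b1, and Creld2 and Sdf2l1 were lowest at 12.8 ± 1.93 and 9.92 ± 2.33. Cytosolic heat shock genes had a median of 7.78 ± 0.04 over 13 members, with the constitutive Hsp90ab1 at 2988 ± 0.276. The inducible Hspa1a and Hspa1b stood at 1.5 ± 0.174 and 4.33 ± 0.211. Sequence shared between genes was not counted for this list. The low values of these inducible genes therefore cannot be told from reads shared with other genes. Of the translation machinery, the elongation factor list had a median of 6.28 ± 0.04 over 10 members and the cap-binding and mTOR list 5.88 ± 0.02 over 24 members, above the eIF2 list by 1.09 ± 0.05. Eef1a2, the elongation factor of neurons and muscle, stood at 1004 ± 33.0, 2.02-fold above Eef1a1 (497 ± 21.8), and Eif4a2 (276 ± 0.215) was 4.05-fold above Eif4a1 (67.5 ± 4.06). Shared sequence was not counted for these genes either, so the folds may partly reflect reads shared with copies. The translation repressor genes Eif4ebp1 and Eif4ebp2 were at 7.71 ± 0.675 and 4.55 ± 0.163.

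Mitochondrially encoded genes lay above, and cytosolic ribosomal protein genes below, the nuclear genes of oxidative phosphorylation. The medians were 9.31 ± 0.12 over 12 of 13 mitochondrial genes, 6.79 ± 0.16 over 33 nuclear oxidative phosphorylation genes and 4.82 ± 0.05 over 79 ribosomal protein genes, with differences of 2.51 ± 0.04 and -1.98 ± 0.11 from the oxidative phosphorylation list; with the mean over members in place of the median the first was 0.68. mt-Cytb (2391 ± 378), mt-Nd5 (1598 ± 222) and mt-Co1 (1567 ± 242) led the mitochondrial list, and Atp5b (990 ± 58.3) and Atp5a1 (658 ± 17.1), which encode subunits of ATP synthase, led the nuclear one. Rpl4 (199 ± 17.3), Rpl27a (178 ± 37.6) and Rpl8 (116 ± 10.3) were the highest ribosomal protein genes, and Rps18 and Rpl39 were lowest at 9.21 ± 1.93 and 6.86 ± 0.738. Much of the sequence of ribosomal protein genes occurs in other genes: the median ribosomal protein gene shared 96.7% of its coding windows of 28 bases with another gene, against 9.24% for oxidative phosphorylation genes. The 32 ribosomal protein genes with no coding window of their own stood between 6.86 and 178 CPM, and whether these reads lay in shared windows, untranslated regions or longer footprints was not told apart. Per kb of unshared coding positions the difference became 0.26, which takes all reads to lie at such positions. The 5 mitochondrial genes with at least 99% of windows shared, mt-Nd3, mt-Co2, mt-Co3, mt-Atp6 and mt-Nd4l, stood between 0.581 and 18.6 CPM, and the other 8 between 311 and 2391.

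**Figure D3:**
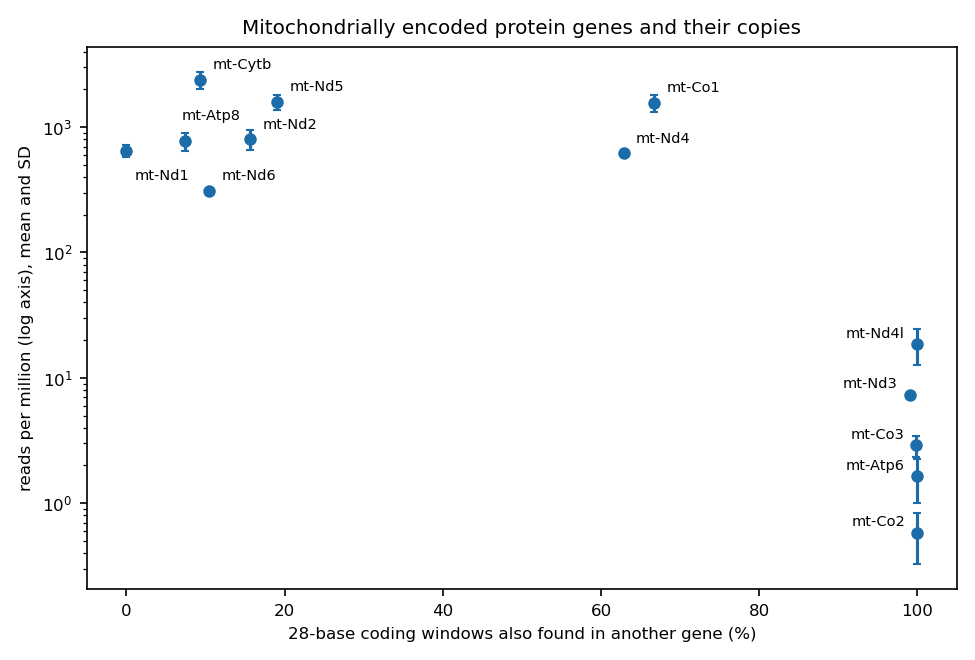
CPM (log axis; mean over the 2 pairs of libraries, bars 1 SD, n = 2) of the 13 mitochondrially encoded protein genes against the percentage of their 28-base coding windows found in another gene. The 5 genes at 99% or more lie at 18.6 CPM or below, the other 8 at 311 or above.

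Genes of nerve injury, neuronal activity and inflammation lay below those of the sensory neuron subtypes. The nerve injury and regeneration list had a median of 4.68 ± 0.13 over 22 of 25 members, the immediate early genes 3.52 ± 0.25 over 16 and the cytokine and inflammatory genes 3.50 ± 0.57 over 13 of 21. The cytokine receptor genes Il6st (739 ± 40.2) and Lifr (593 ± 66.6) and the neuropeptide precursor gene Vgf (251 ± 23.8) led the injury list, while Sox11, a transcription factor gene raised after axon injury, stood at 1.55 ± 0.312. Of the immediate early genes Jun (89.2 ± 7.60) and Nr4a1 (58.2 ± 7.45) were highest and Fosb (1.34 ± 0.252) lowest. Of the inflammatory genes Cxcl12 stood at 42.4 ± 3.10, and Ccl3 and Il10 were listed at 0 in all libraries. The tests of these levels against random lists placed 26 of the 37 lists at or above the 95th percentile, the integrated stress response targets among them at the 97.3rd, and the eIF2, nerve injury, inflammatory and immediate early lists at the 93.4th, 93.3rd, 34.9th and 26.5th.

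Most of these differences pointed one way in every library, but the design cannot pass a threshold. Of the 15 list contrasts 13 had the same sign in all 4 libraries, and so did 22 of the 24 gene contrasts. For each of these the two-sided exact sign-flip permutation test gave p = 0.13, the smallest, rounded, that 4 libraries allow, with adjusted p (Benjamini-Hochberg) of 0.144 over the list contrasts and 0.136 over the gene contrasts. With each pair counted once the smallest p is 0.5. The neuronal and satellite glia lists, and the ribosomal protein and noncoding RNA lists (-0.48 ± 0.68, 1 of 4 libraries higher, p = 0.25 in the same exact test), did not have one sign, and the second of these became 0.29 with no filter, -1.15 with a minimum mean of 10 and -2.52 with genes whose values were whole reads. In the first pair alone it was -0.00091 and in the second -0.96.

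Between the 2 pairs of libraries, muscle, neutrophil and fat genes were higher in the first, and noncoding RNA, pan-neuronal and nociceptor genes higher in the second. Of the 14 skeletal muscle genes 14 were higher in the first pair, by a median of -0.64 on the log2 scale (second minus first pair), with Ttn at 1137 and 1160 CPM in replicates 1 and 2 against 554 and 550 in replicates 3 and 4. Of 11 lymphocyte and neutrophil genes 9 were higher in the first pair (median -1.11), among them the calprotectin genes S100a9 (462 and 462 against 155 and 139) and S100a8 (282 and 284 against 76.6 and 77.8), and the granule protease gene Elane (64.8 and 70.2 against 16.9 and 21.6). Adipocyte genes differed by -0.61 (7 of 8 higher in the first pair), macrophage genes by -0.31 (16 of 17), red blood cell genes by -0.27 (6 of 6) and bone and cartilage genes by -0.21 (7 of 9). The long and structural noncoding RNA list, with a median level of 5.30 ± 0.63 over 15 members, was higher in the second pair by 1.08 (13 of 15 members). In this list the nuclear RNA Malat1 (chromosome 19, 5795690 to 5802672) stood at 274 and 255 against 638 and 669 CPM, and Rn7s2 was listed at 0. Pan-neuronal genes were higher in the second pair by 0.20 (25 of 26), peptidergic genes by 0.32 (8 of 10), non-peptidergic genes by 0.30 (14 of 20) and sodium channels by 0.26 (10 of 13). Large-diameter neuron genes differed by 0.045 (12 of 20 higher in the second pair). The 95% bootstrap interval of this last median was -0.084 to 0.17, which resamples genes and does not measure spread between samples. Ribosomal protein genes differed by -0.13 (62 of 79 higher in the first pair), oxidative phosphorylation genes by -0.19 (30 of 33) and mitochondrially encoded genes by -0.30 (10 of 12). Muscle, neutrophil and fat markers moved the same way as these last 3 groups.

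The members of 19 of 37 lists moved together over the 4 libraries more than 95% of 10000 random lists of matched level did. If genes and lists moved independently, 1.85 lists would be expected. That count is only a guide, because some lists share members and genes of 1 cell type may move together. As the libraries lie in 2 pairs, the measure mostly restates the difference between the pairs. These 19 included the pan-neuronal, peptidergic, non-peptidergic, sodium channel and sensory transduction lists, and the skeletal muscle, lymphocyte and neutrophil, macrophage, red blood cell, adipocyte, mural cell, and bone and cartilage lists. They also included the detoxification list, of which 15 of 19 members were higher in the first pair by a median of -0.15, the same direction as the skeletal muscle (-0.64), lymphocyte and neutrophil (-1.11) and adipocyte (-0.61) markers. The integrated stress response targets (74.8th percentile), endoplasmic reticulum chaperones (48.1st), glycolysis genes (28.0th) and eIF2 genes (4.32nd) were not among them. With 2 samples these differences have no test, and no label names a cause or batch for the pairs.

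**Figure D4:**
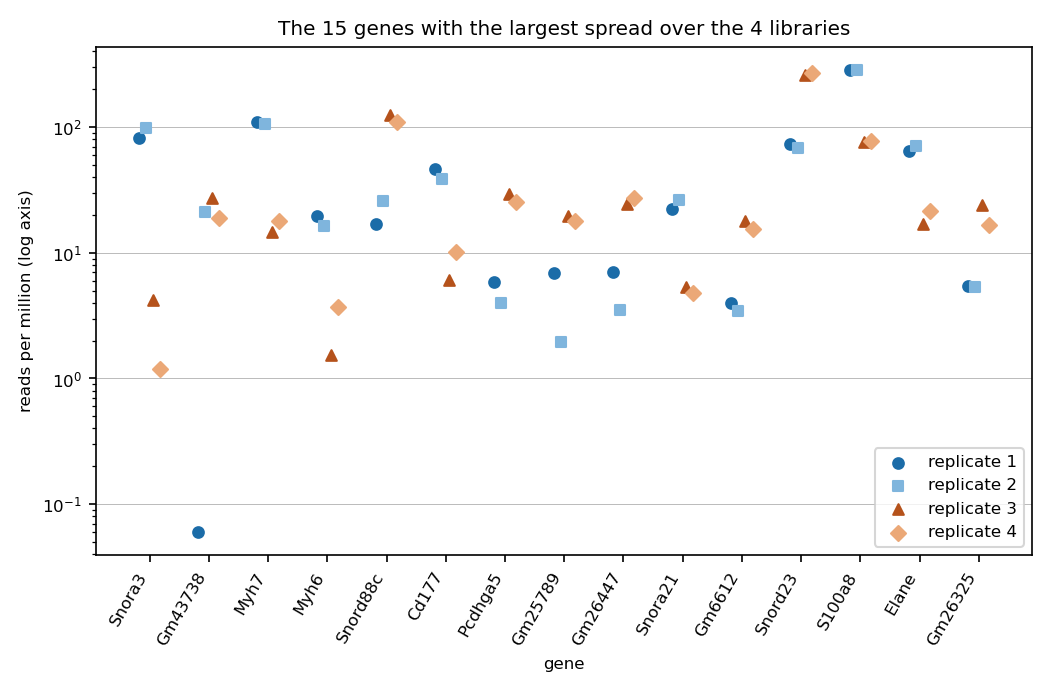
CPM (log axis) in each of the 4 libraries for the 15 genes with the largest SD of log2 values among genes with a mean of at least 10. In most of these genes the 2 pairs lie apart, as in Myh7, and Gm43738 stands at 0.0600 in replicate 1 against 21.2 in replicate 2.

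Some of the single genes with the largest spread were noncoding RNA, myosin and neutrophil genes. Snora3 (chromosome 7, 109520120 to 109520251) stood at 81.6 and 98.0 CPM in the first pair and at 4.20 and 1.20 in the second, and Snord88c and Snord23 went the other way, from 16.9 and 25.8 to 126 and 110, and from 73.1 and 68.7 to 259 and 271. The myosin heavy chain genes Myh7 and Myh6, of slow and cardiac muscle, stood at 110 and 107 against 14.6 and 17.9, and at 19.5 and 16.3 against 1.53 and 3.73. Cd177, a neutrophil surface protein gene, stood at 46.2 and 38.3 against 6.13 and 10.1. Of the 8995 genes with a mean of at least 10, 106 (1.18%) differed over 2-fold between the pair means on the log2(value + 1) scale, 61 of them higher in the second pair and 45 in the first, and 49 were coding genes. Small nucleolar RNAs together held 0.486% of the reads of the first pair and 0.807% of the second, and small nuclear RNAs 0.351% and 0.704%. The splicing RNA Rnu11 alone stood at 1519 and 1551 against 3574 and 3557. Among the least variable genes above 100 CPM were Hsp90ab1, Col4a1, Scn7a and Svep1.

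The sex label was matched by the Y-linked genes. Ddx3y stood at 37.6 ± 0.509, Eif2s3y at 23.9 ± 2.41, Uty at 15.8 ± 4.84 and Kdm5d at 13.6 ± 0.776 CPM, and the list of 4 had a median of 4.38 ± 0.22. Xist, the X-inactivation RNA of female cells, had 0.287 CPM in replicate 1 and 0 in the others, below the floor, and Tsix was listed at 0.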

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

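In 11 of 345 results examined, 1 of the 4 libraries lay far from the other 3, as judged by its gap over the whole range; chance alone flags about 1 in 20 results from independent libraries, or 17.2 of them, but these libraries lie in 2 pairs, so that rate is only a guide. The outlying library is named with each, and none was explained. Replicate 1 stood apart for Creld2 (16.6 CPM against 11.5 to 11.8, gap over range 0.940), Egr1 (44.2 against 34.9 to 35.7, 0.911), P2rx2 (5.16 against 0.380 to 1.07, 0.856) and Xist (0.287 against 0 in the others, 1 read, with a gap over range of 1). Replicate 2 stood apart for Kcnd3 (42.9 against 49.4 to 50.5, 0.861) and for the C-low-threshold mechanoreceptor list (5.46 against 5.66 to 5.69 on the log2 scale, 0.870). Replicate 3 stood apart for Eif2ak4 (16.1 against 11.7 to 12.3, 0.861), the nerve injury and regeneration list (4.42 against 4.75 to 4.77 on the log2 scale, 0.926), mt-Co3 (1.53 against 3.15 to 3.46, 0.840), Gm15662 (4501 against 4103 to 4163, 0.848) and the share of reads on genes outside GENCODE M21 (0.475% against 0.432% to 0.438%, 0.858).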

How the results depend on the processing

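Alternatives using each pair alone, coding length, genes whose values were whole reads or unshared windows were chosen after seeing the data. No paired analysis was possible because the labels give only 1 group. Of the 15 list contrasts, 10 kept their sign in every alternative run, and of the 24 gene contrasts, 21; the tests cannot pass the threshold in any. Neuronal minus satellite glia genes ranged from -0.13 to 0.021 on the log2 scale when 1 replicate was left out, and was 0.11 in the second pair alone and 0.15 with genes whose values were whole reads. With a minimum mean of 10, peptidergic minus non-peptidergic genes became -0.67 and macrophage minus lymphocyte and neutrophil genes -1.31, because fewer and higher members stayed. Ribosomal protein minus oxidative phosphorylation genes became 0.26 per kb of coding positions not shared with another gene, which takes all reads to lie at such positions, and minus noncoding RNA 0.29 with no filter, where low noncoding members enter. Per kb of coding length, Eif2ak3 minus Eif2ak2 became -0.34, Eif2ak3 minus Eif2ak1 -0.41 and Atf4 minus Atf5 -0.16. The number of detected genes was 8995 with a minimum mean of 10. The share of the 10 most abundant genes was 11.5% after rescaling without mitochondrial and listed noncoding genes. The median Pearson's r was 0.960 with a pseudocount of 0.1, 0.984 with 5 and 0.984 with no filter. Of the list levels 428 values kept within the spread and 161 moved beyond it, and of the values of movement together 461 and 17. The number of lists at or above the 95th percentile of level was 20 to 30 and of movement together 15 to 19. Genes near the floor of 0 reads, such as Trib3 and Sox11, rest on a few reads per library, so their folds are not detectable at this depth.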

Other observations

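Some abundant entries of the table lie outside the planned comparisons. Dync1h1, the dynein heavy chain gene of axonal transport, stood at 3366 ± 345 CPM (SD, n = 2), and the spectrin genes Sptan1 and Sptbn1 at 3163 ± 273 and 2794 ± 167. The perlecan gene Hspg2 stood at 2789 ± 337 and Psap, which encodes a lysosomal precursor protein, at 3062 ± 189. Tmem38b stood at 3045 ± 984. Of the 2835 windows of 28 bases of its longest transcript, untranslated regions included, 92 occur in an rRNA gene. For Lars2, 51 of 3867 windows occur in other genes. Only annotated transcripts were compared, so sequence shared with RNA outside the annotation would be missed. These counts therefore do not settle where the reads of Tmem38b and Lars2 came from.

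The tests below were chosen after their results were seen, except that of further muscle and marrow genes, which was written down before. For the pairing of the libraries, that each pair is 1 library read in separate runs cannot be told from 2 libraries of the same material. In genes with 1000 reads or more, chi-square per degree of freedom was 1.21 between replicates 3 and 4 (p = 0.0000342), above sampling noise but far below the 21.6 and more across pairs, and Gm43738 differed within the first pair. It stays open whether the pairs differ by animals, dissection or library preparation, since no label names them. Apart from the shares of cell types weighed below, no biological explanation was tested, because the labels give 1 group.

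For the 106 genes over 2-fold apart between the pairs, a GC content bias acting alike on all transcripts is argued against as the whole cause. The 50 genes nearest to each in GC content had a median difference of at most 0.136 in size on the log2 scale. Median GC was nonetheless 52.5% in the genes higher in the first pair and 48.8% in the others. Only 49 of the 106 genes were coding, and a GC bias particular to noncoding RNA was not tested. A lower share of neurons in the first pair is argued against as the only change in the markers of other cell types. Alone it would raise all of them alike, but the difference of satellite glia minus that of skeletal muscle markers was 0.715 on the log2 scale. Their medians were 0.07 (95% bootstrap interval over genes -0.12 to 0.16) and -0.64 (-0.76 to -0.54). Such intervals resample genes and do not measure spread between samples. A lower share of neurons together with another change is not excluded, as 25 of 26 pan-neuronal genes were higher in the second pair. These medians cover marker lists rather than the 106 genes. More skeletal muscle and marrow cells in the tissue of the first pair may account for the muscle and neutrophil genes: of 43 further genes of these cells, in none of the other lists, 40 were detected and 95% of these (38) were higher there, against 50.5% of all detected genes. They were 25 of 26 muscle, 7 of 7 neutrophil and 6 of 7 red blood cell genes, led by Ltf, Neb and Pygm at 188, 169 and 167 CPM. The red blood cell genes alone do not decide: their median difference was -0.20, and the 95% binomial interval of the share was 42.1% to 99.6%. The fixed lists of these cells already lay higher in the first pair of the same libraries. These further genes are therefore not an independent test. Noncoding RNA lies outside that hypothesis and its difference stays open.

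For the mitochondrial and ribosomal protein genes, reads shared with copies are a candidate explanation of low values. The highest of the 5 mitochondrial genes with at least 99% of windows shared was 18.6 CPM, against 311 for the lowest of the other 8. Their closest copies were at 0 CPM for mt-Co2, 0.143 for mt-Co3 and 6.88 for mt-Nd3, which itself had 7.35, so where such reads were counted stays open. For the 79 ribosomal protein genes shared reads cannot be told from a lower level, because Spearman's rho of shared windows and CPM per kb was -0.231 with a 95% bootstrap interval over genes of -0.452 to 0.0204. The 5 genes with at most 50% of windows shared had a median of 151 CPM per kb, as did 25 oxidative phosphorylation genes (151), but these are few, and no biological explanation was tested.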
